A study of Caenorhabditis elegans with 2 samples.

How the data were processed

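The series holds GFP chromatin immunoprecipitation sequencing of SMA-3, the receptor-regulated Smad of the worm BMP-like pathway, in whole Caenorhabditis elegans L2 hermaphrodites. Per the labels, the animals carried an integrated transgene for GFP-tagged SMA-3 with a rol-6 marker in a sma-3 mutant background, and were collected 24 hours after release from starvation-synchronised L1 arrest. The labels give 2 biological replicates of this 1 group. Per the listing deposited with each sample, each replicate had its own list of regions, called from that replicate's alignment and 1 control alignment shared by both replicates. A pooled list came from both alignments and the same control, and the optimal list was derived from these by an irreproducible discovery rate (IDR) procedure. The aligner, the peak caller, their versions, thresholds and read depths are not given in the sources used here. The signal tracks and alignments named in the listing are not used here.

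Each list was deposited on the genome builds ce10 and ce11. Column 7 of each list holds the signal value that the authors' peak caller gave a region, whose scaling is not given in the sources used here. It served only to rank regions within a list and to describe them. Column 9 holds the authors' −log10 q, which reached the same highest value in 6361 of the 30000 pooled ce11 regions and therefore ranked nothing among the optimal peaks. Each replicate list and the pooled list hold exactly 30000 regions, most of them background that the IDR procedure takes as input. The optimal ce11 list was identical to the 4205 highest-signal regions of the pooled list. Of its intervals, 25 repeat an interval already listed, with another summit, and each summit was kept as a peak. Depth is unknown, so intervals given here cover counting of regions or genes only.

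Analyses used the ce11 lists, with genes from Ensembl release 115 (assembly WBcel235) and the RefSeq sequence of the same assembly. Every region ended within the length of its chromosome in that sequence. No coordinate was converted between builds, and the ce10 lists entered only comparisons of ranks and counts and the overlap of the ce10 replicate lists with each other. A promoter window ran from 1000 bp upstream to 200 bp downstream of any of 29314 annotated transcription start sites of 19973 protein-coding genes. A gene had a promoter peak when a summit lay in a window of one of its start sites. Summits in no window were placed in coding exons, UTRs or introns of protein-coding genes, or outside them. Lowest-ranked regions were the 6000 at the bottom of the pooled list (20%). Random placements moved each peak within its chromosome, 100 draws for promoter windows and the replicate overlap and 20 for the other locations.

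Replicates were compared by the share of the 4205 highest-signal regions of replicate 1 that overlapped one of the 4205 highest of replicate 2 by at least 1 bp. In the plot of their signal, each region is paired with the highest-signal region it overlapped. A further comparison of the replicates is not reported here. Promoter shares were compared with Fisher's exact test and X and autosome densities with an exact binomial test. The 23 gene lists, the 13 motifs, their tests, the replicate, promoter and X density comparisons and most alternatives were fixed before the data were examined. The test of non-coding classes, and the comparisons of X with the lowest-ranked regions and of promoter shares on X, were added after the lists had been opened. Each list was tested against all other protein-coding genes with Fisher's exact test, adjusted over the lists by Benjamini and Hochberg's method. Odds ratios had 0.5 added to each cell. 1 symbol of the lists had no gene in the annotation. Non-coding classes, 9 in number, were compared by summits within 100 bp. Motifs were searched on both strands in the 151 bp around each summit and in a window of the same width centred 600 bp away on a random side, and compared with an exact McNemar test adjusted over the motifs. This left out 78 peaks whose control window overlapped another summit window or ran off the chromosome. All tests were two-sided. Intervals are 95% exact (Clopper-Pearson) intervals, except exact Poisson intervals for densities.

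Genes named in the text are the 20 with the highest-signal promoter peak whose peak overlapped a region among the 4205 highest of each replicate, with a summit in windows of several genes given to the nearest start site. To these come all members of the BMP list, up to 3 members with the highest-signal promoter peak of every other list, and sma-3 and rol-6 because the transgene carries them. Other genes named were chosen after their values were seen. Computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

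The tests were checked on simulated data. In the gene list test, run on 19973 genes in 50 simulations, a planted peak share of 40% was called in 74% of simulations for the BMP list, and in 100% for the ribosomal protein and cuticle collagen lists. Of lists with nothing planted, 0.889% were called. Each gene was given a peak independently of its neighbours. The simulation therefore did not cover calls that arise from peaks shared by neighbouring genes or from clustered list members. In the motif test, run on 4205 windows in 10 simulations, GTCTG planted in 5% of windows and the SMAD/Schnurri element planted in 0.5% were called in 100% of simulations, and 0% of motifs with nothing planted were. Both sides of that simulation were shuffles of the same flanking sequences. It therefore did not cover calls that arise from the different GC content of summit and control windows. In the replicate overlap, all of the regions left in place among 106 were recovered, and 0% of those moved. A region left in place always overlaps itself, so this checked only the counting of overlaps.

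The alternatives were a reciprocal overlap of 50%, summits within 100 bp, the higher-ranked part of the regions, the ce10 lists, promoter windows of 500 and 2000 bp upstream, and only peaks among the highest regions of both replicates. Each replicate was also left out by using the 4205 highest regions of the other alone. For gene lists, further alternatives assigned peaks to the nearest start site only, compared each list with 10000 random lists matched on deciles of the distance to the next gene upstream, or counted members within 5000 bp of each other once. For motifs, they used dinucleotide-shuffled summit windows as the control, windows of 50 and 150 bp on either side, or only summits in promoter windows. The alternative of peaks in or within 5000 bp of a gene was chosen after seeing the data.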

Results

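SMA-3 acts downstream of the DBL-1 ligand and its receptors, a BMP-like pathway that sets body size in Caenorhabditis elegans, and enters the nucleus with SMA-2 and SMA-4. The regions recovered with it in L2 larvae came from immunoprecipitating a GFP fusion from whole animals in 2 biological replicates. Each replicate gave 30000 ranked regions, and the optimal set held 4205 peaks on ce11. Pooled signal over these peaks ran from 70.1 to 1762, with a median of 121 and a median width of 400 bp. Signal is the authors' value per region and is given to rank peaks within a list. There is 1 group, so the comparisons are between replicates, between peaks and background regions, and between gene groups. No untagged immunoprecipitation was analysed here. Recovery of active promoters irrespective of SMA-3 therefore remains open for all peaks and gene lists below.

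The question of whether the replicates gave the same regions was addressed first. The promoters of rpl-3 and rpl-15, which encode ribosomal proteins, ranked 1 and 2 in both replicates and in the pooled list. Of the 4205 highest regions of replicate 1, 3422 (81.4%, 95% exact interval 80.2 to 82.5%) overlapped the 4205 highest of replicate 2, against a mean of 2.91% and a maximum of 3.5% over 100 random placements. The share was 81.6% among the 250 highest regions and 63.9% among all 30000. Of the optimal peaks, 87.8% overlapped the 4205 highest regions of replicate 1, 91.6% those of replicate 2 and 80.3% both. The optimal peaks were derived from these same replicates by the IDR procedure, so this overlap is partly built in and is no separate evidence of agreement. A reciprocal overlap of 50% lowered the shared share to 70.8%.

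**Figure D1:**
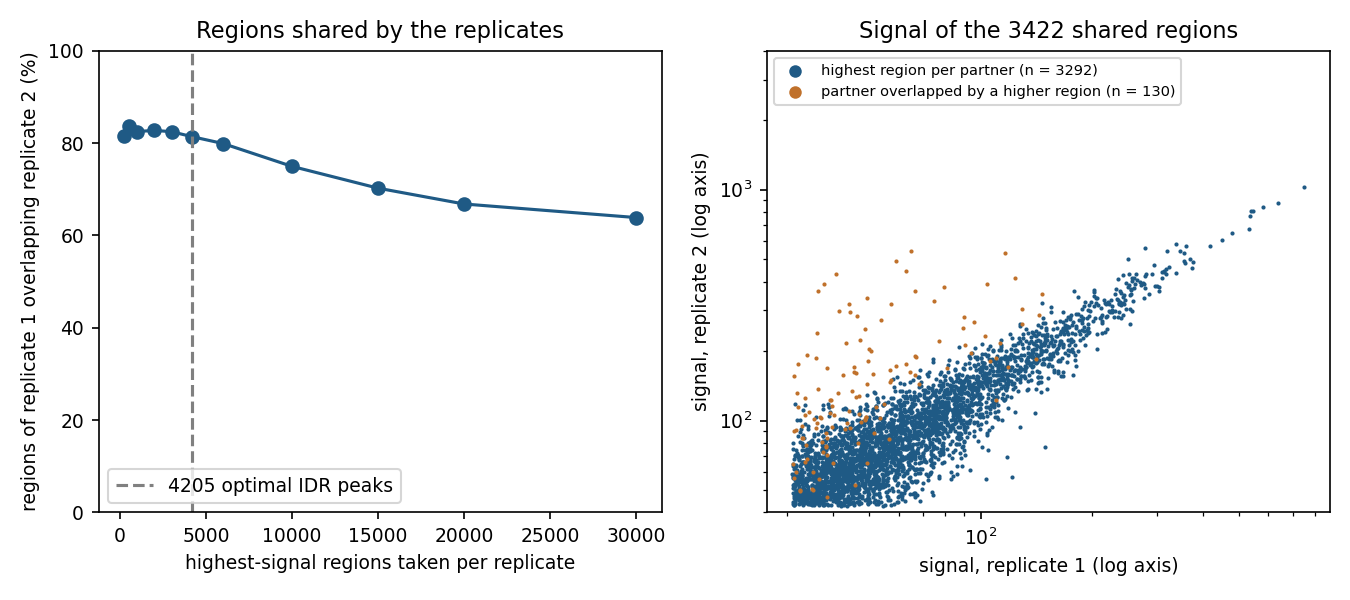
Left, the share of replicate 1 regions (%) that overlap replicate 2 against the number of highest-signal regions taken per replicate, which stays between 79.9% and 83.8% up to 6000 regions and is 63.9% at 30000. Right, signal in both replicates (log axes) for the 3422 shared regions, 1 point per region, with the 130 regions whose partner is also overlapped by a higher replicate 1 region in orange; these include all 26 points over 3 times the median ratio.

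Optimal peaks lay mostly just upstream of protein-coding genes. Of the 4205 summits, 2357 fell in promoter windows (56.1%, interval 54.5 to 57.6%), compared with 27.6% of the lowest-ranked regions (two-sided Fisher's exact test, p = 2.88e-185) and 25.7% on average under random placement. Among summits in promoter windows, 93.3% were upstream of the start site, at a median of -199 bp. Coding exons outside promoter windows held 1.97% of summits, compared with 25.1% of the lowest-ranked regions, and introns held 15.3%, compared with 26.9%. Intergenic sequence held 25.4%, compared with 16.5% of the lowest-ranked regions and 25% under random placement, so its share was close to the random one. In all, 2863 of 19973 protein-coding genes (14.3%) had a promoter peak, and 673 peaks served more than 1 gene.

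**Figure D2:**
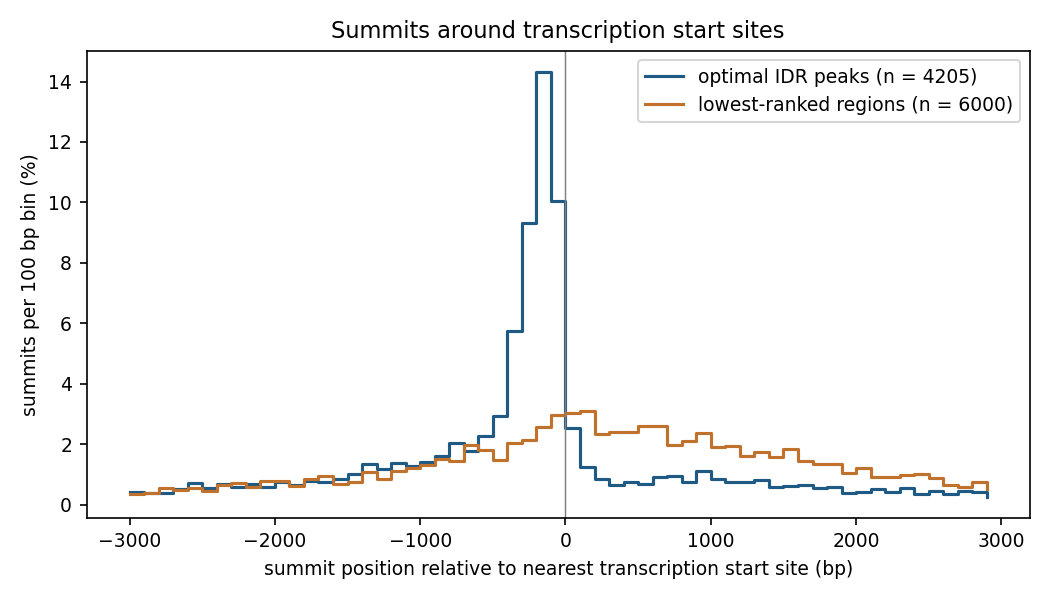
Summits per 100 bp bin (%) by position relative to the nearest transcription start site, for the 4205 optimal peaks and the 6000 lowest-ranked regions. Optimal summits pile up just upstream, and the lowest-ranked regions show no such pile-up.

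The 20 genes with the highest promoter peaks were led by the ribosomal protein genes rpl-3 and rpl-15. The peak of rpl-3 (III, 3867322 to 3867748) had a summit 290 bp upstream of the start site and a signal of 1762, and that of rpl-15 (IV, 654729 to 655101) a signal of 1496. Next came cdc-48.1, which encodes the AAA ATPase p97, with a signal of 1353, then tasp-1 with 1333, Y17G9B.5 with 1294, rpl-35 with 1181 and iff-2, a gene for translation factor eIF5A, with 1123. The peak assigned to Y17G9B.5 lay 304 bp upstream of the divergently transcribed rpl-20 as well. The Pumilio-family gene puf-9 (signal 1045) and the cytochrome oxidase gene cox-5A (994) followed, then tag-340, drr-2, egg-5, tos-1, his-37, cmtr-1, hsr-9, the CBP/p300 gene cbp-1, sma-2, serp-1.1 and sec-61.G, with signals from 780 to 921. The hsr-9 peak lay in the window of rps-19 as well. The highest peak outside a promoter window ranked 3 (signal 1402) and lay in an intron on V, at 19529181 to 19529564, 2590 bp into Y43F8B.2. All 20 peaks ranked 39 or higher in replicate 1 and 29 or higher in replicate 2.

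Members of the BMP pathway itself had a promoter peak more often than other genes. Of 20 members, 8 had a promoter peak (40%, interval 19.1 to 63.9%), compared with 14.3% of other genes (log2 odds ratio 2.03, two-sided Fisher's exact test, adjusted over 23 lists, p = 0.0146). The highest was at sma-2, which encodes a Smad partner of SMA-3, on III at 8749423 to 8749886, with its summit 84 bp upstream, a signal of 831 and ranks of 17 and 19 in replicates 1 and 2. The others were the transcription cofactor sma-9 (246), the LRIG-family gene sma-10 (225), the tetraspanin gene tsp-21 (205), unc-40 (149), the type I receptor gene sma-6 (121), adt-2 (81.6) and the ADAM10-family gene sup-17 (76). The sma-10 peak lay in the window of srh-282 as well. The 12 members without a promoter peak were bra-1, bra-2, crm-1, daf-4, dbl-1, drag-1, lon-1, lon-2, sma-3, sma-4, tsp-12 and tsp-14. With only the 2102 highest peaks the exact adjusted p was 0.0715, and over all 10 alternatives it ranged from 0.000245 to 0.0715.

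Some of these members carried peaks farther from their start sites. At lon-1, a target of this pathway that restrains body length, the highest peak ranked 117 (signal 496), with its summit at 5472933 on III in intergenic sequence 1543 bp upstream, and 3 further peaks lay within 5000 bp upstream. The strongest peak near sma-9 ranked 79 (signal 559) and lay 2904 bp upstream on X, at 10766378, and an intronic peak had a signal of 265. At sma-4, the common Smad gene, summits lay 1302 and 3431 bp upstream, the nearer one in another gene's promoter window. Peaks in the gene or within 5000 bp of it were also counted, a distance chosen after seeing the data. By this count 15 of 20 members had a peak (75%, interval 50.9 to 91.3%), compared with 38.6% of other genes (Fisher's exact test, adjusted p = 0.006). The peaks counted for bra-1, drag-1 and tsp-12 all lay in other genes' promoter windows. The transgene's genes, sma-3 and rol-6, lay in region-free stretches of 34993 and 24678 bp in the pooled list. The stretches were 19074 and 23026 bp in the list of replicate 1, and 33131 and 23387 bp in that of replicate 2. In the pooled list, stretches at least as long held 16.8% and 25.3% of protein-coding genes.

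Ribosomal protein genes had the highest share of the 23 lists, and further growth and housekeeping lists passed the test. Of 78 cytosolic ribosomal protein genes, 66 had a promoter peak (84.6%, interval 74.7 to 91.8%), compared with 14.1% of other genes (log2 odds ratio 5.02, Fisher's exact test, adjusted p = 9.16e-43), and the adjusted p stayed at or under 0.00153 in all 10 alternatives. With each peak assigned to the nearest start site only, the log2 odds ratio fell to 2.89. Vacuolar ATPase subunits had 9 of 20 (45%, exact adjusted p = 0.00435), led by vha-12 (signal 414), vha-8 (321) and vha-1 (226). The heat shock list had 7 of 20 (35%, exact adjusted p = 0.0362), among them the constitutive chaperone genes hsp-1 (744), hsp-60 (643) and hsp-90 (605). The vha-8, vha-1, hsp-60 and hsp-90 summits each lay nearer another gene's start site. Histones had 16 of 50 (32%, exact adjusted p = 0.00619), led by his-37 (853) and the divergent pair his-67 and his-68, which share a peak (489). The pairs his-3 and his-4, his-31 and his-32, his-35 and his-41, his-59 and his-60, and his-61 and his-62 each share a peak too. The test counted each gene. With members within 5000 bp counted once, 7 of 19 had a peak (Fisher's exact test, adjusted p = 0.0292). The heat shock call was lost in 6 of the 10 alternatives, the histone call in 3 and the vacuolar ATPase call in 1.

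Regulators of epidermal fate and developmental timing also had promoter peaks more often than other genes. Of 19 genes, 9 had a promoter peak (47.4%, interval 24.4 to 71.1%; log2 odds ratio 2.44, Fisher's exact test, adjusted p = 0.00342), led by myrf-1 (signal 247) and the heterochronic genes lin-28 (238) and lin-14 (204). Fatty acid and lipid genes had 19 of 75 (25.3%, exact adjusted p = 0.0275), led by the lipid-binding protein gene lbp-9 (177), the nuclear receptor gene nhr-49 (170) and the acetyl-CoA carboxylase gene pod-2 (160). The call was lost in 2 of 10 alternatives for the first list and in 4 for the lipid list, including with the peaks of replicate 2 alone (exact adjusted p = 0.185). Over all alternatives the exact adjusted p ranged from 0.00059 to 0.175 and from 0.00022 to 1.

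The cuticle collagen list did not differ from other genes. A promoter peak was found at 23 of 176 collagen genes (13.1%, interval 8.47 to 19%), compared with 14.3% of other genes (log2 odds ratio -0.13, Fisher's exact test, adjusted p = 0.857), with the highest peaks at col-63 (signal 303), col-38 (269) and col-71 (197). The col-38 peak lay in the window of rpl-5 as well, and the col-71 summit lay nearer another gene's start site, at 134 bp. Of 11 collagen-processing genes, 3 had one, pdi-2 (181), dpy-11 (138) and dpy-31 (97.8), at an exact adjusted p of 0.356. Molting genes had 2 of 17, mlt-3 and lrp-1 (exact adjusted p = 1), and the parallel dauer TGF-beta pathway had 1 of 7, daf-5 (adjusted p = 1). Nuclear hormone receptors had 45 of 269 (16.7%, exact adjusted p = 0.391), with nhr-68 (628), nhr-119 (432) and nhr-142 (292) highest. The nhr-68 and nhr-142 summits lay nearer another gene's start site, at 43 and 171 bp. The nuclear hormone receptor list passed above other genes in 2 of 10 alternatives, nearest start site only (exact adjusted p = 0.0394) and clusters counted once (0.0302), in a range of 0.0302 to 1. Homeobox genes of the ceh class had 3 of 63, ceh-38, ceh-20 and ceh-13 (exact adjusted p = 0.0554), and passed the threshold in 3 alternatives.

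Promoter peaks were rarer than elsewhere in 4 lists. Chemoreceptor genes had 15 of 1298 (1.16%, interval 0.648 to 1.9%; log2 odds ratio -3.90, Fisher's exact test, adjusted p = 3.68e-66), with srh-2 (signal 470), srh-16 (298) and srh-76 (279) highest. Innate immune effectors had 25 of 340 (7.35%, exact adjusted p = 0.000662), with the highest peak shared by the antimicrobial peptide genes nlp-31 and nlp-34 (291), then clec-126 (217). Neuropeptide and insulin genes had 9 of 140 (6.43%, exact adjusted p = 0.0147), led by ins-39 (563), and share 8 members with the immune list. Of these 8 nlp genes, nlp-27, nlp-29, nlp-31, nlp-33 and nlp-34 had a promoter peak, and nlp-28, nlp-30 and nlp-32 had none. The low share of the immune list therefore did not hold for each of its gene families, which were not tested separately. Hedgehog-related genes had 4 of 85 (4.71%, exact adjusted p = 0.0197), grl-26, wrt-3, ptr-6 and grl-11. The calls for neuropeptides and hedgehog-related genes were each lost or turned in 4 of 10 alternatives. None of the cell type marker lists passed the test (lowest exact adjusted p = 0.389), with 2 of 11 hypodermal markers (col-10, elt-3), 1 of 13 intestinal (elt-2), 1 of 11 muscle (unc-60), 2 of 12 neuronal (snb-1, unc-31), 0 of 10 pharyngeal and 0 of 12 germline genes; the interval for 0 of 12 reached 26.5%.

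**Figure D3:**
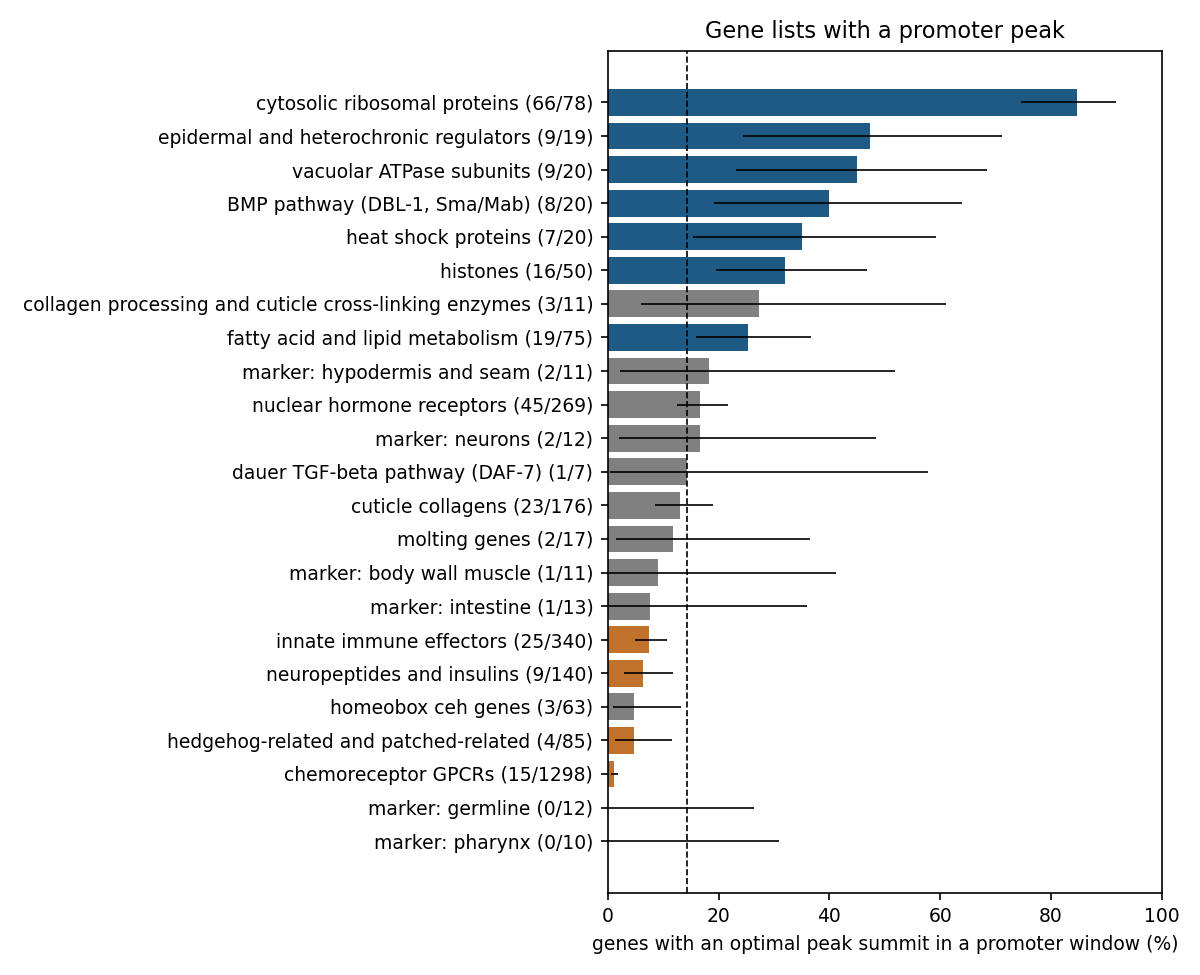
Genes with a promoter peak (%) per gene list, with members counted beside each name and 95% exact intervals as lines; blue and orange bars passed the test above and below other genes, grey bars did not, and the dashed line marks all protein-coding genes (14.3%). Ribosomal proteins reach 84.6% and chemoreceptors 1.16%.

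Transfer RNA genes stood out among non-coding genes. A summit lay within 100 bp of 250 of 612 tRNA genes, involving 239 peaks (5.68%, interval 5 to 6.43%), compared with 0.183% of the lowest-ranked regions (Fisher's exact test, adjusted p = 1.32e-77). Small nucleolar RNA genes were near 2.26% of summits, compared with 0.217% (exact adjusted p = 1.1e-23), and small nuclear RNA genes near 0.904%, compared with 0.05% (adjusted p = 1.1e-11). Other ncRNA genes were near 13.4% and 2.4% (exact adjusted p = 2.54e-102). Pseudogenes were near 0.523% of summits, below the 1.87% of the lowest-ranked regions (exact adjusted p = 1.43e-09), as were piRNA genes (0.38% and 1.08%, adjusted p = 8.5e-05). Long intergenic RNA genes were near 0.547% and 0.233% (exact adjusted p = 0.0149). MicroRNA and antisense RNA genes did not differ (exact adjusted p = 0.514 and 0.821).

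Peaks were denser on X than on the autosomes. X held 893 peaks, or 50.4 per Mb (exact Poisson interval 47.1 to 53.8), and the autosomes ranged from 32.1 per Mb on V to 49.6 on III. The density on X was 1.26 times that of the autosomes (exact binomial test, p = 3.44e-09), whereas among the lowest-ranked regions it was 0.869 times (p = 6.02e-05), and the sets differed (Fisher's exact test, p = 1.21e-12). On X, 44.6% of summits lay in promoter windows, compared with 59.1% on autosomes (Fisher's exact test, p = 1.01e-14).

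Sequences known to bind Smad proteins were more frequent at summits than 600 bp away, over 4127 pairs of windows. GTCTG was present in 24.4% of summit windows and 14.7% of control windows (two-sided exact McNemar test, adjusted over 13 motifs, p = 3.21e-28), CAGACA in 12.7% and 5.45% (adjusted p = 9.67e-31) and the GC-rich GGCGC in 23.6% and 6.95% (adjusted p = 8.83e-103). The Mad site GCCGNCGC was in 2.37% and 0.533% (exact adjusted p = 1.35e-12). The palindrome GTCTAGAC occurred in 8 summit and 7 control windows (exact adjusted p = 1). Motifs of other factors were also above control. GAGA repeats were in 8.77% and 0.969% (exact adjusted p = 5.07e-67), the E-box CACGTG in 9.43% and 3% (adjusted p = 1.75e-33) and the GC box in 8.48% and 2.67% (adjusted p = 9.67e-31). GATA sites were in 36.3% and 28.9% (exact adjusted p = 1.49e-12), AP-1 sites in 2.81% and 1.45% (adjusted p = 2.2e-05), nuclear receptor sites in 6.35% and 3.88% (adjusted p = 5.19e-07) and BLMP-1-like sites in 3.05% and 1.7% (adjusted p = 7.65e-05). In all, 12 of 13 motifs passed. CAGACA contains the reverse complement of GTCTG, so every window with CAGACA also counts as a window with GTCTG. Summit windows had 43.4% GC and control windows 36.1%. Against dinucleotide-shuffled summit windows GTCTG was in 24.3% and 21.6% (exact adjusted p = 0.00471, range over 8 alternatives 5.44e-29 to 0.00471), a fall of the log2 ratio of discordant pairs from 0.90 to 0.23. The same control lowered this log2 ratio from 1.35 to 0.80 for CAGACA, from 2.15 to 1.04 for GGCGC, which 14.7% of shuffled windows held, and from 2.18 to 0.83 for the Mad site, and these calls held. Among motifs of other factors, it went from 0.48 to 0.91 for GATA, from 1.72 to 1.71 for the E-box and from 1.73 to 1.83 for the GC box, and fell from 3.30 to 2.76 for GAGA repeats and from 0.99 to 0.50 for AP-1. The BLMP-1-like site (exact adjusted p = 0.495, range 7.46e-05 to 0.495) and the nuclear receptor site (adjusted p = 0.137, range 8.92e-08 to 0.137) no longer passed. AP-1 did not pass with the 2102 highest peaks (exact adjusted p = 0.247, range 4.88e-07 to 0.247). Against shuffled windows, GTCTG was in 1021 summit and 910 shuffled windows, and CAGACA in 535 and 331. GTCTG without CAGACA was therefore not more frequent at summits than in shuffled windows, and was not tested separately.

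**Figure D4:**
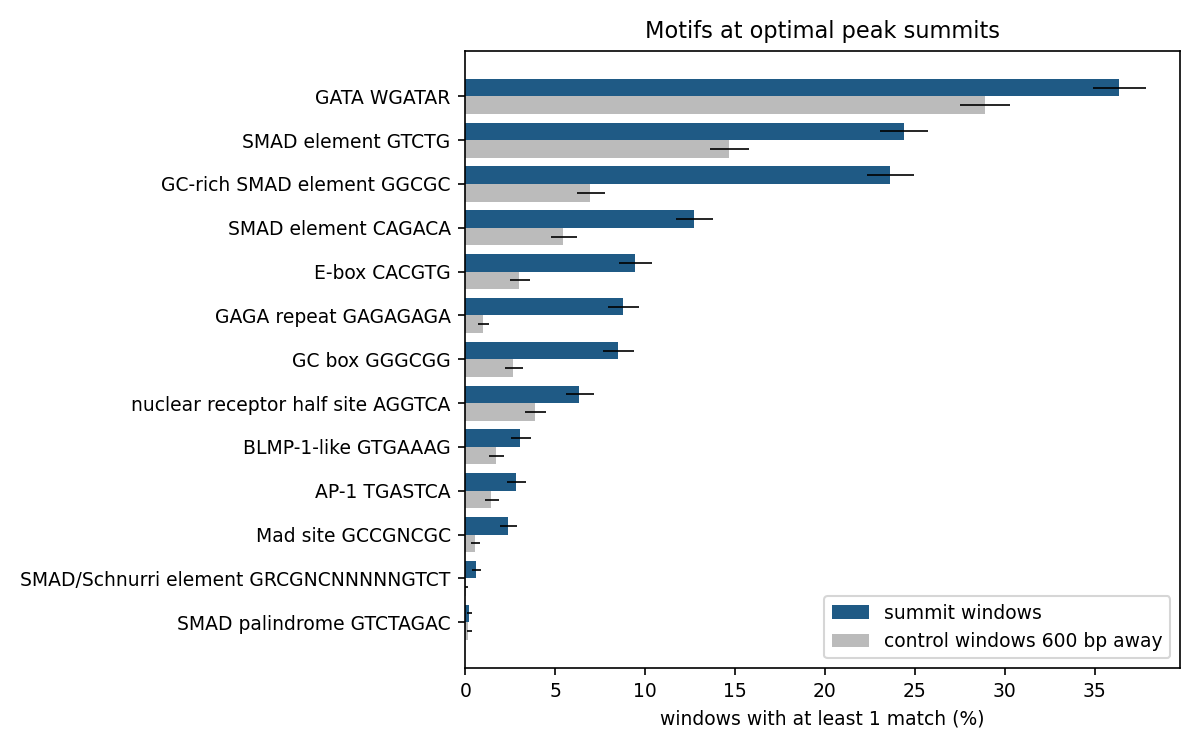
Windows with at least 1 match (%) for 13 motifs in 4127 summit windows (blue) and paired control windows 600 bp away (grey), with 95% exact intervals as lines. Only the palindrome GTCTAGAC shows no difference.

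A composite of a GC-rich Smad site and GTCT 5 bp apart, the arrangement that recruits Smad and Schnurri proteins in flies, was rare but concentrated at summits. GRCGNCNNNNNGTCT occurred in 24 of 4127 summit windows and 2 control windows (log2 ratio of discordant pairs 3.29, exact McNemar test, adjusted p = 1.36e-05). Against dinucleotide-shuffled windows it occurred in 26 and 6 windows (log2 ratio 2.03, exact adjusted p = 0.000994, range over 8 alternatives 2.76e-06 to 0.00494). Over all 4205 peaks it was in 26 windows, and in 22 of them it was centred within 50 bp of the summit. The highest-ranked were at an intron of Y62E10A.13 on IV (rank 111; GACGCCTCTGCGTCT at 13395379 to 13395393), at srh-2 on V (rank 131; GGCGTCTCTTCGTCT at 731487 to 731501) and 268 bp upstream of T28B8.1 on I (rank 247; GGCGTCTCTGCGTCT at 8133800 to 8133814). The peak 1863 bp upstream of crm-1, the BMP list member related to crossveinless, held GGCGTCGAAATGTCT on V at 10333965 to 10333979. These genes were chosen after their values were seen.

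**Figure D5:**
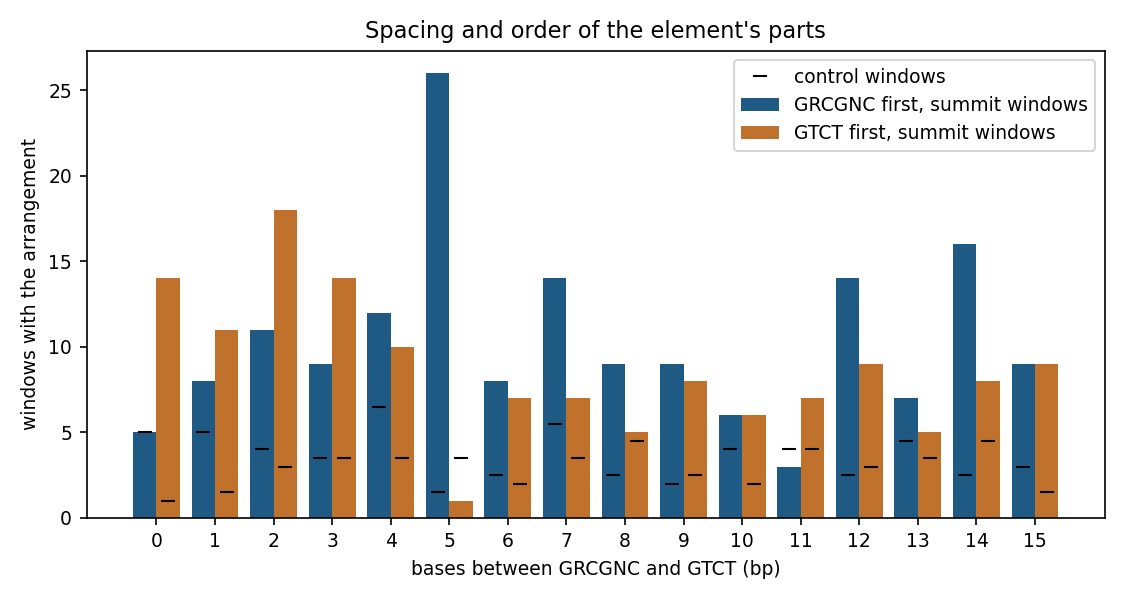
Summit windows (bars) with GRCGNC and GTCT at each spacing from 0 to 15 bp, in either order, with the mean of control windows on both sides as dashes. The 5 bp spacing with GRCGNC first has 26 windows, and no other arrangement exceeds 18.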

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

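The regions ranked from 4206 to 5405 in the pooled ce11 list lie below the ce11 optimal set but within the number of peaks that the ce10 optimal list holds. Of these 1200 regions, 27.9% (interval 25.4 to 30.5%) overlapped the 5405 highest regions of both replicates, compared with at most 4% in 100 random placements. The pooled list came from the alignments of these same replicates, so overlap above random placement is partly built in. Of the optimal peaks, 80.3% overlapped the 4205 highest regions of both replicates. In promoter windows lay 49.9% of the 1200 regions (interval 47 to 52.8%), below the 56.1% of the optimal peaks and above the 27.6% of the lowest-ranked regions.

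The tests below were chosen after the result was seen. The ce10 optimal list holds 5405 peaks and the ce11 list 4205, a ratio of 1.29. A different range of signal in the pooled lists does not account for this, since over the 5405 highest regions the signal at the same rank differed between builds by at most 0.826%. Regions were not matched between builds, so this cannot exclude a different order of regions. The replicates showed no better overlap on ce10, since 81.4% of their highest regions were shared on both builds. This overlap does not measure how well their ranks agree, so it cannot exclude better agreement in rank on ce10. Different settings or versions of the IDR step remain open and were not tested. No biological explanation was tested, since both lists describe the same animals.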

How the results depend on the processing

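The direction and test of the promoter share held in all 6 alternatives (46.4 to 68.7%), as did the X to autosome ratio in all 4 (1.13 to 1.25). The number of motifs above control stayed between 10 and 12 in 8 alternatives, and the GTCTG and SMAD/Schnurri calls held in each. Against shuffled windows, GTCTG without CAGACA was not more frequent at summits. With replicate 1 left out, the lipid list lost its call and the homeobox list gained one, and with replicate 2 left out the heat shock list lost its call. The shared share fell to 70.8% with a reciprocal overlap of 50% and to 76.2% with summits within 100 bp, which are stricter by construction. The higher-signal part of the optimal list held 2102 peaks by construction. It left 2 lists above other genes, and the BMP list at a log2 odds ratio of 1.96 (exact adjusted p = 0.0715); peaks among the highest of both replicates left 4 lists above, compared with 7. Assigning peaks to the nearest start site only, or matching on upstream distance, each left 2 lists below, compared with 4. The hedgehog-related list turned to a log2 odds ratio of 0.0198 with peaks within 5000 bp (chosen after seeing the data) and the BLMP-1-like motif to -0.13 against shuffled windows. For these changes the cause was not tested. For lists that passed, 85 alternative values kept the call and 25 lost it, and for the others 5 gained one; for motifs that passed, 93 kept it and 3 lost it. No paired analysis was possible because there is 1 group. Read depth is unknown, so what it limits cannot be stated; lists of 20 genes or fewer have wide intervals.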

Other observations

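Of the tests below, all except the one on upstream distance were chosen after the result was seen. Peaks at tRNA and ribosomal protein genes differed in sequence from the remaining 3903 peaks. GTCTG was in 36.8% of the 239 peaks near tRNA genes, compared with 23.6% of the remaining peaks (two-sided Fisher's exact test, adjusted over 26 tests, p = 0.000154), and CAGACA was in 5.44%, compared with 13.2% (adjusted p = 0.00111). Their E-boxes were rarer, 1.26% against 10% (exact adjusted p = 4.04e-06), and their GAGA repeats too, 2.93% against 9.2% (adjusted p = 0.00156). The windows of these peaks can include tRNA gene sequence, and whether that sequence itself holds or lacks these motifs was not tested. The tests counted each peak as independent, which similar gene copies would not be. The 63 ribosomal protein promoter peaks held GGCGC in 44.4%, compared with 22.9% (exact adjusted p = 0.00111), and GATA sites in 12.7%, compared with 37.4% (adjusted p = 0.000258). Their median pooled rank was 789, and that of peaks near tRNA genes 2306.

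The promoter peaks at 84.6% of ribosomal protein genes could in part reflect gene spacing, but random lists matched on upstream distance had a peak at 19.5% of genes on average (permutation test, adjusted p = 0.00153, from the smallest p that 10000 lists give, 0.0002), which argues against spacing as the whole cause. Recovery of highly active promoters irrespective of SMA-3 remains open. CAGACA was in 7.94% of these peaks (interval 2.63 to 17.6%), not above the 13.2% of the remaining peaks, and the absence of a motif excludes neither explanation. An untagged immunoprecipitation and expression values, which would separate them, are not analysed here. No biological explanation was tested.

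The SMAD/Schnurri element was in 26 summit windows. Base composition does not account for it, since 100 dinucleotide-shuffled sets of the same windows held it 5.05 times on average and 10 times at most. Chance meeting of its parts does not either, since none of the 31 other spacings and orders up to 15 bp exceeded 18 windows, with a median of 9. Copies of a repeat that extends beside the element do not account for it, since in all 26 windows the 40 bases beside the element shared under 60% with every other window (45% at most). The bases within the element were not compared, so a short recurrent sequence that holds it is not excluded. The elements of the peaks ranked 111, 247, 252 and 544 all end in CTGCGTCT. A hypothesis that these data leave standing is recruitment of SMA-3 through this arrangement at a small number of sites, which may be tested by mutating the element.

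The labels differ on where the tag sits, since the strain's construct is written with GFP before sma-3 and a note places the tag at the other end of the protein. No value here depends on it.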
